A study of Mus musculus with 9 samples.

How the data were processed

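Gene expression was measured by RNA sequencing in whole heart tissue of male C57BL/6J mice aged 18 to 20 weeks in 3 groups of 3: sham-operated mice, mice after an operation that the labels call TAC, an abbreviation usually read as transverse aortic constriction, and TAC mice given Lingguizhugan decoction (LD), a Chinese herbal preparation. By the sample titles, the sham mice and the TAC mice without decoction were treated with distilled water. Per the labels' protocols, total RNA was taken from 3 biological repeats, mRNA was selected with poly-T beads and libraries were made with random hexamer priming, with no step named that marks the strand. The labels name no litter, cage, operation day, collection time or sequencing batch.

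Per the submitters' processing notes, the tools used were CASAVA 1.8, fastp 0.20.0, HISAT2 2.1.0, HTSeq 0.7.2, Cufflinks 2.2.1 and DESeq, and the genome build was GRCm38. Which tool made which value, and the annotation, are not given in the sources used here. The deposited table holds FPKM values (fragments scaled by gene length and library total) of 21989 gene symbols in 9 columns, each matched to 1 sample by its name. Of these symbols, 5727 were listed at 0 in every library, and 20667 occur in GENCODE M21, which gave coordinates, GC content and exon overlaps on GRCm38. Older symbols such as Wisp2 and Ctgf were kept as the table gives them. The table lists no mitochondrially encoded gene.

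FPKM values of a gene were whole multiples of the worth of 1 fragment, so library totals and gene lengths were recovered from the deposited FPKM values. All 16262 genes above 0 came out as whole fragments within a tolerance of 0.001, which put the library totals between 7.43 and 18.1 M fragments and at least 99.9% of each total in listed genes. The smallest length that gave whole fragments was taken, a weak check for genes above 0 in few libraries. Of 12058 genes compared with annotated exon lengths, 46.0% had a recovered length within 25% of it (median log2 ratio -0.215). A gene of 1 kilobase with 3 fragments would have an FPKM of 0.166 in the deepest library and 0.404 in the shallowest. Such limits cover counting error only.

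Values were analysed as log2(FPKM + 1), so a log2 difference understates the change of low genes. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries (11380) were tested with limma 3.58.1 in R 4.3.3: 1 mean per group, all 3 groups in 1 fit with 6 residual degrees of freedom, empirical Bayes with a trend, moderated two-sided tests, Benjamini-Hochberg adjusted p under 0.05. A moderated F test asked whether any group differed. Gene lists (50, fixed before the data were examined, as were the tests, the rule for named genes and most alternatives) covered heart failure programmes, signalling, metabolism and other cell types. The 47 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; the lists of mitochondrially encoded genes (0 measured members), neutrophil markers (4) and B cell markers (3) were not. Camera asks whether a list stands apart from all other genes. Beside it stand camera with an estimated correlation, which allows for members that vary together, and limma's fry, whose directional test asks whether members move on balance one way and whose mixed test asks whether they change in either direction.

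Genes were named by a rule: those past the threshold whose groups did not overlap, with a mean FPKM of at least 1. Because fewer than 5 passed in each direction, the 5 genes of smallest p in each direction are named, said not to pass, beside a fixed set of heart failure and kinase genes and up to 4 members of smallest p of each list described. A gene named in 1 comparison may be given in another: Comp, Wisp2, Cilp and Bgn in LD against TAC, chosen after their values were seen. Predicted genes without a proper symbol were counted, not named, and a few genes that the rule names are not reported here. Errors of log2 differences are limma's standard errors; errors of FPKM are SDs over 3 mice.

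Simulated values took the real genes' means and limma's moderated spread, for TAC against sham on 11380 genes with 200 changed genes. The fit called 32% of 50 genes changed 2-fold and 100% of 50 each changed 4-fold, 8-fold and 16-fold. Of 182 calls, 15 were false. A list shifted by 0.5 on the log2 scale passed camera with an adjusted p of 6.1e-09 at the preset and 0.019 with an estimated correlation. Simulated errors were independent between genes, no library stood apart, and low genes were left unchanged. The moderated spread also holds the most variable genes closer to the common trend than their own values do. These rates therefore need not hold for the real libraries, where members of a list vary together. Alternatives changed the pseudocount, the filter, the scaling, the fit and its weights, and left out each library in turn. Chosen after seeing the data were limma's voom, without and with sample quality weights, on the recovered fragments, removal of each library's trend on gene length and GC content, and leaving out TAC replicate 3 and LD replicate 3 together. Other splits of the libraries into groups of the same sizes were also fitted.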

Results

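The study measured poly-A RNA of the heart in 9 mice: 3 after a sham operation, 3 after TAC, an operation that loads the left ventricle with pressure, and 3 after TAC that were given Lingguizhugan decoction (LD). By its title the study asks how this decoction acts in heart failure, with the MAPK and AKT pathways in view. Recovered library totals were 18.1, 14.5 and 14.9 M fragments in sham, 8.40, 14.9 and 8.96 M in TAC, and 7.43, 18.1 and 16.1 M in LD, for replicates 1, 2 and 3. Replicates of a group correlated between 0.913 and 0.973 (Pearson's r of log2 values across genes). The first principal component (29.4% of the variance) set TAC replicate 3 at -51.0 and LD replicate 3 at 48.3, while the other 7 libraries lay between -10.4 and 17.1. LD replicate 3 also had a median log2 value 0.24 below the sham mean, so that the median gene differed by -0.10 between LD and TAC. This shift was 0.01 after median-of-ratios scaling and -0.20 after rescaling to equal sums.

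TAC against sham asks what the operation did to the heart. Genes of the fibrillar matrix and of activated fibroblasts rose as groups in TAC, while basement membrane genes did not (median -0.05, camera adjusted p = 0.98). Myofibroblast markers had a median log2 difference of 1.11 (18 of 20 measured members above 0, 13 with unadjusted p under 0.05; camera adjusted p = 1.54e-17, and adjusted p = 0.126 with an estimated correlation). Fibrillar collagen and matrix genes had a median of 0.64 (39 of 42 above 0; adjusted p = 1.52e-22, and 0.199 as the adjusted p with an estimated correlation). Among the genes of smallest p were several matrix genes. Comp, a cartilage matrix protein (chromosome 8, 70373558 to 70382066 on GRCm38), had a mean FPKM of 20.0 ± 9.10 (SD, n = 3) in TAC and 2.61 ± 1.0 in sham, a log2 difference of 2.50 ± 0.36 (SE; adjusted p = 0.0856). Wisp2, a secreted matricellular protein, stood at 35.9 ± 12.7 against 9.37 ± 0.925 (log2 1.78 ± 0.27, adjusted p = 0.0856), the proteoglycan Bgn at 405 ± 127 against 151 ± 6.55 (1.36 ± 0.24) and the matrix protein Cilp at 27.9 ± 18.9 against 3.49 ± 0.691 (2.44 ± 0.45). Fmod (1.77 ± 0.33) and the latent TGF-beta binding protein Ltbp2 (1.68 ± 0.41) had no overlap between the groups either. The major collagens moved less, with log2 differences of 0.31 ± 0.29 for Col1a1 and 0.44 ± 0.42 for Col3a1. Postn, a matrix gene of activated fibroblasts, ranged from 11.4 to 194 FPKM over the TAC libraries (log2 1.88 ± 0.72). Fibroblast markers rose (median 0.65, 20 of 20 above 0; adjusted p = 6.65e-14, and 0.199 as the adjusted p with an estimated correlation), among them Tcf21 (1.08 ± 0.26) and Dcn (1.09 ± 0.28). Means of the fibroblast list were 0.19, 0.02 and -0.21 in sham and 0.21, 0.91 and 0.92 in TAC replicates 1, 2 and 3. Those of the matrix list were 0.226, -0.101 and -0.125 in sham and 0.266, 0.961 and 1.323 in TAC. In both lists TAC replicate 1 stood close to sham replicate 1. TGF-beta pathway genes (median 0.24), led by Ltbp2 and Tgfb3 (0.80 ± 0.28), matrix proteases and inhibitors (0.25), with Timp1 at 1.48 ± 0.41, and complement and coagulation genes (0.46), with C1ra at 0.64 ± 0.27, rose as well. Their adjusted p were 5.75e-05, 0.00487 and 8.17e-06 at the preset, and the adjusted p with an estimated correlation were 0.365, 0.277 and 0.126. The TGF-beta median was 0.10 without TAC replicate 3, and the protease median 0.43 without TAC replicate 1. Postn differed by 2.84 without TAC replicate 1 and 0.85 without TAC replicate 3, and Timp1 by 0.98 without sham replicate 2.

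The fetal gene programme, a set of genes that the stressed heart muscle switches back on, also rose in TAC (median 0.31, 15 of 21 above 0; adjusted p = 0.000183, and adjusted p = 0.405 with an estimated correlation). Its mean over members was 0.13, 0.48 and 0.79 in TAC replicates 1, 2 and 3, and its median was 0.47 without TAC replicate 1 and 0.12 without TAC replicate 3. Skeletal actin, Acta1 (chromosome 8, 123891769 to 123894751), averaged 944 ± 550 FPKM in TAC and 142 ± 48.4 in sham (log2 2.57 ± 0.44, adjusted p = 0.129). The natriuretic peptide gene Nppa stood at 253 ± 180 against 72.3 ± 14.7 (1.53 ± 0.49), Nppb at 59.9 ± 20.9 against 28.8 ± 7.64 (0.99 ± 0.43), and the stretch-responsive genes Ankrd1 and Xirp2 differed by 1.11 ± 0.36 and 1.19 ± 0.42. Without TAC replicate 3, Nppa, Ankrd1 and Xirp2 differed by 0.98, 0.67 and 0.61. Myh6, the adult alpha myosin heavy chain, was at 2603 ± 334 against 3766 ± 275 with no overlap (-0.54 ± 0.24), while Myh7, the fetal beta chain, differed by 0.18 ± 0.33 and the calcium pump gene Atp2a2 by -0.26 ± 0.23.

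**Figure D1:**
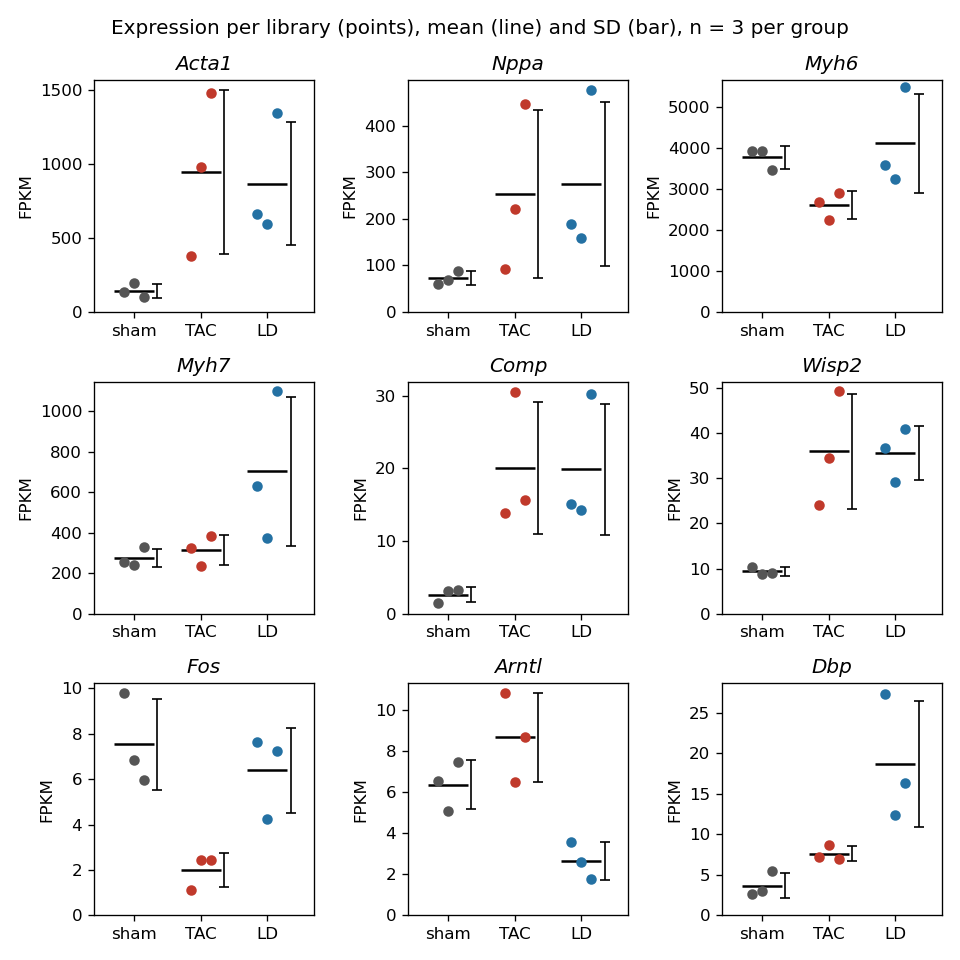
FPKM (linear axes from 0) of 9 genes in each library of the sham, TAC and LD groups, with the group mean as a line and the SD as a bar to its right (n = 3). Acta1, Comp and Wisp2 lie higher in all TAC and LD libraries than in all sham libraries, Fos is lowest in the 3 TAC libraries, and Arntl is lowest and Dbp highest in the 3 LD libraries.

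Immediate early genes, which respond within minutes to a stimulus, fell in TAC (median -0.34, 18 of 25 below 0, 11 of these with unadjusted p under 0.05; adjusted p = 3.58e-06, and adjusted p = 0.405 with an estimated correlation). Their change in either direction passed fry's mixed test (adjusted p = 0.048), as did that of the myofibroblast markers (adjusted p = 0.048). Fos was at 2.01 ± 0.756 FPKM against 7.53 ± 2.0 in sham (log2 -1.51 ± 0.31), the phosphatase gene Dusp1 at -1.29 ± 0.29, the nuclear receptor gene Nr4a1 at -1.68 ± 0.42 and Btg2 at -0.96 ± 0.25, all with no overlap. The list's median was -0.52 without TAC replicate 3. Fatty acid oxidation (median -0.26; adjusted p = 0.000596, and 0.277 as the adjusted p with an estimated correlation) and PPAR targets (-0.29; adjusted p = 0.0156, and 0.298 as the adjusted p with an estimated correlation) fell at the preset. Nuclear-encoded oxidative phosphorylation (-0.19, 66 of 75 below 0; adjusted p = 0.000609, and 0.7 as the adjusted p with an estimated correlation) and cardiac ion channels (-0.24; adjusted p = 0.0102, and 0.365 as the adjusted p with an estimated correlation) fell too. Among their members were Esrra (-0.61 ± 0.24), Acads (-0.70 ± 0.34), Acot1 (-1.06 ± 0.34, and -0.67 without TAC replicate 3), Plin5 (-0.59 ± 0.22) and the potassium channel genes Kcnj5 (-0.77 ± 0.25) and Kcnd3 (-0.93 ± 0.34). Without TAC replicate 3, fatty acid oxidation (median -0.09), PPAR targets (-0.03) and oxidative phosphorylation (-0.04) no longer passed. Calls also ended for oxidative phosphorylation without sham replicate 2 (-0.12), for PPAR targets without TAC replicate 2 (-0.18) or sham replicate 2 (-0.26), and for ion channels without TAC replicate 1 (-0.29) or sham replicate 1 (-0.21). The PPAR median was -0.19 without sham replicate 1 or 3. Glucocorticoid-responsive genes fell (median -0.20; adjusted p = 0.0276, and 0.682 as the adjusted p with an estimated correlation), a call that held in 11 of 23 other alternatives, with medians from -0.42 to 0.01. Its median was -0.42, -0.12 and -0.07 without sham replicates 1, 2 and 3 and -0.17, -0.32 and -0.10 without TAC replicates 1, 2 and 3, and the call held only without sham replicate 1 or TAC replicate 2 among these 6. It also ended without LD replicate 3 (adjusted p = 0.0541).

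Other genes with small p and lower values in TAC were the adrenaline-forming enzyme gene Pnmt (1.30 ± 0.576 against 6.18 ± 1.55 FPKM), the histone gene Hist1h3d, the kinetochore gene Pmf1, and Upk1a (chromosome 7, 30603092 to 30612847). Upk1a had 0 fragments in all 3 TAC libraries, against 52, 29 and 42 in sham. With the limit of 3 fragments over the TAC group it was at least 27.5-fold lower in TAC. Among markers of blood and immune cells, erythroid genes rose (median 1.30; adjusted p = 1.74e-06, and 0.389 as the adjusted p with an estimated correlation), with Hbb-bs at 1.5 ± 0.56 and Hba-a1 at 1.35 ± 0.63. The means of the erythroid list were -1.02, 0.27 and 0.74 in sham and 0.67, 2.41 and 0.29 in TAC replicates 1, 2 and 3, and its median was 0.59 without sham replicate 1 and 0.60 without TAC replicate 2. Haemoglobin genes took 1.96% of the FPKM sum in TAC replicate 2 and at most 0.633% elsewhere. Macrophage markers (median 0.26, with Mrc1 at 1.0 ± 0.35), interferon response genes (0.28) and epicardial markers (0.28) rose at the preset, with adjusted p of 0.432, 0.714 and 0.365 with an estimated correlation. The macrophage, interferon and epicardial calls held in 22 of 23, 20 of 23 and 17 of 22 other alternatives. The macrophage call ended without TAC replicate 2 (median 0.14) and the interferon call without TAC replicate 1 (0.08) or sham replicate 2 (0.16). The interferon median was 0.46 without sham replicate 1, and 0.56 and 0.15 without TAC replicates 2 and 3. The epicardial call ended without sham replicate 3 (0.29) and without TAC replicates 2 (0.29) and 3 (0.39), while its median was 0.50 without sham replicate 2 and 0.56 without TAC replicate 1. Without sham replicate 1 and without TAC replicate 2, Hbb-bs differed by 0.82 and 0.83 and Hba-a1 by 0.60 and 0.63, and Mrc1 by 0.66 without sham replicate 3. The interferon list had a mean of -0.28 in TAC replicate 2 and the epicardial list -0.08 in TAC replicate 1. Endothelial markers (median 0.16, camera adjusted p = 0.143) and smooth muscle markers (0.16, adjusted p = 0.146) did not pass.

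In all, 17 of 47 lists passed in TAC against sham, 11 higher and 6 lower, and none did with an estimated correlation or by fry's directional test. Several lists share members, such as Ltbp2 in the matrix and TGF-beta lists and Timp1 in the matrix and protease lists. The lists passed are therefore not separate results, here or in the other comparisons. No single gene passed limma's adjusted threshold, where 618 of 11380 genes had an unadjusted p under 0.05 (324 higher, 294 lower; about 569 by chance, and as many in 4 of 10 groupings of these libraries, the real one included) and 1120 genes (9.84%) had no overlap between the groups (10% by chance). Voom on the recovered fragments called 4 genes (Acta1, Bgn, Comp and Wisp2), voom with quality weights 6, and the fit without TAC replicate 1 called 13 (1 without TAC replicate 2 or sham replicate 3). Adjusted over the list alone, 12 of the 20 myofibroblast markers, 13 of the 42 matrix genes and 8 of the 25 immediate early genes (7 lower, 1 higher) passed.

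**Figure D2:**
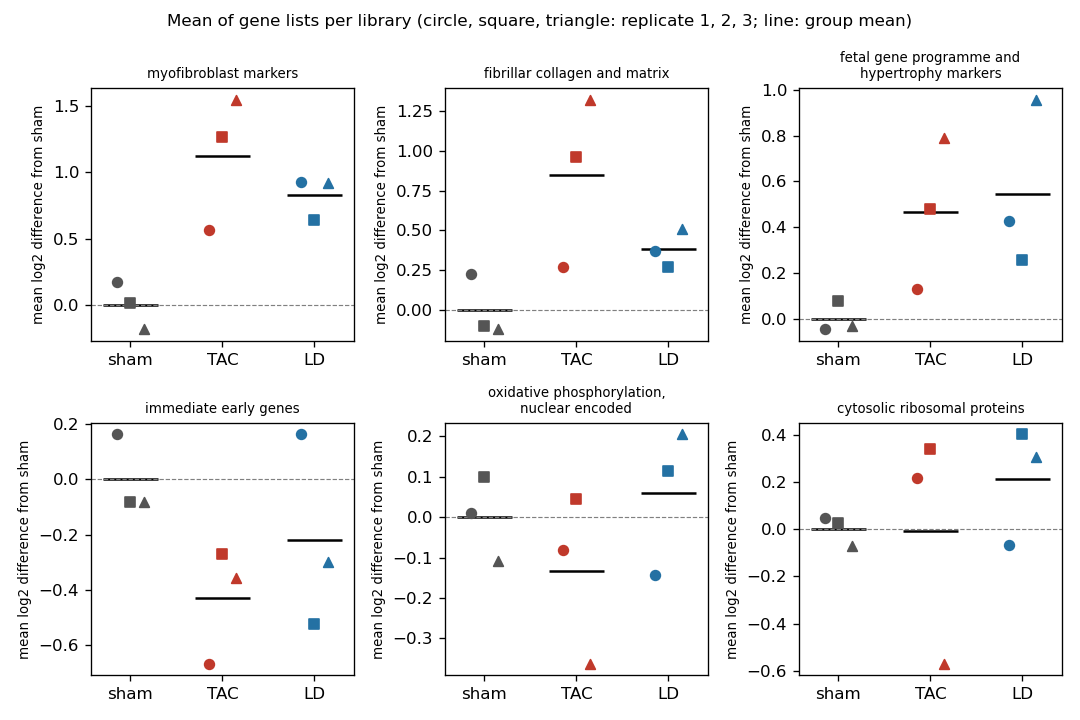
Mean log2 difference from the sham mean over the members of 6 gene lists, 1 point per library (shape gives the replicate number) and a line at each group mean. Matrix genes reach 0.96 and 1.32 in TAC replicates 2 and 3 and 0.27 to 0.51 in TAC replicate 1 and the LD libraries, while ribosomal protein genes are lowest, at -0.57, in TAC replicate 3.

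LD against TAC asks what the decoction changed in operated mice, against distilled water. Matrix genes fell in LD (median -0.50, 39 of 42 below 0; camera adjusted p = 6.72e-05, and adjusted p = 0.712 with an estimated correlation). Adjusted over the list alone, 1 of these 42 genes passed. The list's means were 0.27, 0.96 and 1.32 above sham in TAC replicates 1, 2 and 3 and 0.37, 0.27 and 0.51 in LD, and its median was -0.78 without TAC replicate 1 and -0.25 without TAC replicate 3 (adjusted p = 0.0496). P4ha1, which hydroxylates collagen, averaged 10.6 ± 2.01 FPKM in LD and 22.7 ± 1.76 in TAC (log2 -1.04 ± 0.24), the small proteoglycan Dcn 342 ± 81.7 against 686 ± 239 (-0.97 ± 0.28), elastin, Eln, 49.2 ± 15.2 against 96.7 ± 35.0 (-0.94 ± 0.28) and Timp1 4.32 ± 0.861 against 11.2 ± 4.83. Fibroblast markers fell (median -0.54; Tcf21 -0.85 ± 0.26) and TGF-beta pathway genes fell (-0.27; Smad6 -1.18 ± 0.30, Skil -0.91 ± 0.29), with adjusted p of 0.000684 and 0.009, and both had adjusted p = 0.712 with an estimated correlation. Myofibroblast markers, which had the larger rise in TAC, did not pass (median -0.16 beside -0.10 for the median gene; adjusted p = 0.343). Interferon response genes (-0.56; Ifit1 -1.39 ± 0.48, Gbp2 -0.91 ± 0.32), the unfolded protein response (-0.27; Manf -0.93 ± 0.30, Sel1l -0.97 ± 0.33), complement and coagulation (-0.47; Thbd -1.07 ± 0.31) and erythroid markers (-1.14; Hbb-bs -1.39 ± 0.56) fell at the preset as well. Their adjusted p with an estimated correlation were 0.718, 0.712, 0.712 and 0.724. The interferon, unfolded protein, complement and erythroid calls held in 21, 21, 16 and 21 of 23 other alternatives. Without TAC replicate 2 the fibroblast, TGF-beta, unfolded protein, complement and erythroid lists did not pass, with medians of -0.43, -0.27, -0.31, -0.37 and -0.41, so only the erythroid median moved by over 1.5 times there. Without TAC replicate 3 the TGF-beta (-0.15) and complement (-0.28) calls ended and the fibroblast median was -0.32. Without TAC replicate 1 the interferon call ended (-0.38) and the TGF-beta and unfolded protein medians were -0.46 and -0.41. Without LD replicate 1 the unfolded protein (-0.34), erythroid (-1.10) and complement (-0.44) calls ended, and without LD replicate 2 the TGF-beta (-0.23) and complement (-0.42) calls. Without LD replicate 3, Sel1l and Gbp2 differed by -0.56 and -0.53, while without TAC replicate 2 Ifit1 differed by -2.10 and Hbb-bs by -0.73. Of the genes with a large excess in TAC, between LD and TAC Comp differed by -0.01 ± 0.36, Wisp2 by 0.03 ± 0.27 and Acta1 by -0.02 ± 0.44 (95% interval -0.97 to 0.93), while Cilp differed by -0.51 ± 0.45, Postn by -0.86 ± 0.72 and Bgn by -0.62 ± 0.24. Without TAC replicates 1 and 3 these were -1.13 and -0.02 for Cilp and -1.82 and 0.17 for Postn. Cilp differed by -0.82 without LD replicate 3, Postn by -0.51 without LD replicate 2, and Bgn by -0.40 without TAC replicate 2.

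Lists of the contractile apparatus and of parts of energy supply passed camera higher in LD than in TAC with all libraries included. Fatty acid oxidation (median 0.13, camera adjusted p = 0.0519) and branched-chain amino acid and ketone catabolism (0.15, camera adjusted p = 0.2385) did not pass. Sarcomere genes had a median of 0.20 (18 of 25 above 0; adjusted p = 0.000224, and 0.712 as the adjusted p with an estimated correlation), with Myom2 at 226 ± 46.4 against 131 ± 32.0 FPKM (log2 0.79 ± 0.26), Myl3 at 0.73 ± 0.28 and Tnni3 at 0.53 ± 0.22. Myh6 stood at 4110 ± 1206 against 2603 ± 334 with no overlap (0.63 ± 0.24), and Myh7 at 703 ± 368 against 315 ± 74.1 (1.05 ± 0.33). Without LD replicate 3 the sarcomere call ended (median 0.03), Myh6 differed by 0.40 and Myh7 by 0.66. That library also stood highest in atrial light chains (Myl7 42.3 FPKM, Myl4 27.0) and in the mean of atrial myocyte markers (0.40). Oxidative phosphorylation (median 0.23, 62 of 75 above 0; Ndufs1 0.47 ± 0.23), the tricarboxylic acid cycle (0.26; Idh2 0.57 ± 0.29), glycolysis (0.14; Pdk2 0.61 ± 0.24), cytosolic ribosomal proteins (0.20; Rps14 0.56 ± 0.26) and replication-dependent histones (1.02; Hist1h1c 1.20 ± 0.42) rose. The adjusted p with an estimated correlation were 0.712 for these lists, and 0.724 for ribosomal proteins. With TAC replicate 3 and LD replicate 3 both left out, the sarcomere, oxidative phosphorylation, tricarboxylic acid cycle and histone lists no longer passed. Medians were then -0.05 for glycolysis and -0.04 for ribosomal proteins. Without TAC replicate 3 alone the median was 0.13 for oxidative phosphorylation, 0.17 for the tricarboxylic acid cycle and 0.35 for histones, and the glycolysis (0.06) and ribosomal protein (-0.03) calls ended. Without LD replicate 3 alone the tricarboxylic acid cycle (0.18), glycolysis (0.06) and histone (0.89) calls ended. Without TAC replicate 1 the tricarboxylic acid cycle call ended (0.17), glycolysis had 0.26 and ribosomal proteins 0.31. Without TAC replicate 2 glycolysis had 0.28, ribosomal proteins 0.35 and histones 0.54. Without LD replicate 1 the tricarboxylic acid cycle had 0.40, glycolysis 0.32 and ribosomal proteins 0.35, and without LD replicate 2 ribosomal proteins had 0.12. Myl3, Idh2 and Pdk2 differed by 0.47, 0.24 and 0.36 without TAC replicate 3, and Rps14 by 0.29 without LD replicate 3.

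Immediate early genes, lower in TAC, rose in LD against TAC (median 0.23; adjusted p = 0.00603, and adjusted p = 0.724 with an estimated correlation; fry mixed adjusted p = 0.00848). Fos was at 6.38 ± 1.85 FPKM (log2 1.29 ± 0.31), Nr4a1 at 1.56 ± 0.42, Dusp1 at 1.01 ± 0.29 and Zfp36 at 0.81 ± 0.24, all with no overlap between LD and TAC. The list's means from sham were -0.67, -0.27 and -0.36 in TAC and 0.16, -0.52 and -0.30 in LD replicates 1, 2 and 3, so only LD replicate 1 stood above all TAC libraries. The list's call ended without LD replicate 1 (median 0.11) and without TAC replicate 1 (0.09), and its median was 0.38 without LD replicate 2 or TAC replicate 2 and -0.02 with library weights. Glucocorticoid-responsive genes changed in either direction (fry mixed adjusted p = 0.00438; camera adjusted p = 0.047, held in 8 of 23 other alternatives, and 0.724 as the adjusted p with an estimated correlation). The camera call ended without sham replicate 1, TAC replicate 1 or 3, or LD replicate 1, with medians of 0.02, 0.03, -0.25 and -0.05 beside 0.02 with all libraries, and the median was 0.15 without TAC replicate 2, and 0.06 and 0.22 without LD replicates 2 and 3. Of these, Rasd1 (5.85 ± 2.32 against 0.706 ± 0.612 FPKM, log2 2.02 ± 0.37) and Lcn2 (1.56 ± 0.36) lay higher and Pdk4, an inhibitory kinase of pyruvate dehydrogenase, lower (298 ± 16.8 against 553 ± 147, -0.85 ± 0.24). Core clock genes changed in either direction too (fry mixed adjusted p = 0.00438). Arntl, a core clock transcription factor (chromosome 7, 113207465 to 113314126), averaged 2.64 ± 0.913 in LD and 8.68 ± 2.17 in TAC (-1.42 ± 0.29), while Dbp (chromosome 7, 45705088 to 45710203) stood at 18.7 ± 7.80 against 7.60 ± 0.939 (1.13 ± 0.32), Nr1d1 at 1.06 ± 0.30 and Per1 at 0.89 ± 0.29.

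The genes of smallest p in LD against TAC, none past the threshold, were on the higher side Pglyrp1, an antibacterial peptidoglycan-binding protein (3.13 ± 1.65 against 0.124 ± 0.108 FPKM), Rasd1, Upk1a, Gchfr, the feedback regulator of GTP cyclohydrolase (12.6 ± 4.71 against 1.79 ± 1.94), and Haghl. Upk1a was back at 1.94 ± 0.468 FPKM, at least 27.2-fold above the limit in TAC. On the lower side were Arntl, the endothelial transcription factor gene Sox7 (6.08 ± 1.02 against 17.0 ± 3.75), Klhl2, the ubiquitin-conjugating enzyme gene Ube2c (1.69 ± 0.362 against 5.46 ± 0.524) and Plek2. The smallest adjusted p by limma over all genes was 0.317. None of 11380 genes passed by limma or by either voom fit, 1004 had an unadjusted p under 0.05 (286 higher, 718 lower; about 569 by chance, and as many in 4 of 10 groupings of these libraries, the real one included, with up to 1602) and 1351 (11.9%) had no overlap, where chance gives 10%. The median gene differed by -0.10, and by 0.01 after median-of-ratios scaling, so the surplus of lower genes cannot be told apart from this shift. Of 47 lists 15 passed, 8 higher and 7 lower, 9 with TAC replicate 3 and LD replicate 3 both left out, and none with an estimated correlation or by fry's directional test.

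LD against sham asks what still differed in treated mice. Myofibroblast markers (median 0.65, 15 of 20 above 0; adjusted p = 1.27e-12, and adjusted p = 0.453 with an estimated correlation), the fetal gene programme (0.34; adjusted p = 1.70e-08, and 0.538 as the adjusted p with an estimated correlation) and matrix genes (0.33; adjusted p = 8.41e-07, and 0.590 as the adjusted p with an estimated correlation) rose. Comp averaged 19.9 ± 9.01 FPKM (log2 2.49 ± 0.36, adjusted p = 0.0667), Wisp2 35.5 ± 5.98 (1.81 ± 0.27, adjusted p = 0.0667) and Acta1 866 ± 413 (2.55 ± 0.44, adjusted p = 0.145). The matrix genes Thbs4 (11.4 ± 2.37 against 1.02 ± 0.880, log2 2.69 ± 0.55), Fmod (1.55 ± 0.33) and Cilp (1.92 ± 0.45), and Ankrd1 (1338 ± 346 against 456 ± 136, 1.56 ± 0.36), Nppa (1.75 ± 0.49), Nppb (1.42 ± 0.43) and Myh7 (1.23 ± 0.33) were higher with no overlap, while Myh6 differed by 0.09 ± 0.24. LD replicate 3 held Myl7 and Myl4 at the values above, against at most 7.51 and 7.22 in the other 8 libraries, and the highest Nppa, Myh7 and Myh6 of its group. Without it Nppb differed by 0.86.

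Sarcomere genes (median 0.18; Csrp3 0.69 ± 0.26, Myom2 0.69 ± 0.26), cytosolic ribosomal proteins (0.26; Rpl34 0.52 ± 0.24), replication-dependent histones (0.56; Hist1h1c 0.90 ± 0.42), fibroblast markers (0.16; Pi16 0.76 ± 0.26) and smooth muscle markers (0.12; Myh11 0.77 ± 0.25, Tagln 0.73 ± 0.30) rose, and oxidative stress genes (0.07), glycolysis (0.13) and oxidative phosphorylation (0.03, and -0.08 after quantile normalization) passed on the higher side. Cardiac ion channels (-0.26; Kcnd2 -0.89 ± 0.32) and PPAR targets (-0.26; Pdk4 -0.69 ± 0.24) fell. Among these lists the adjusted p with an estimated correlation lay between 0.453 and 0.795. Libraries were made from poly-A RNA, which limits what the values of histone genes can show, here and in the other comparisons. The call held in 7 of 23 other alternatives for glycolysis, 13 for oxidative phosphorylation, 16 for smooth muscle markers and PPAR targets, and 18 for oxidative stress genes. Without LD replicate 3 the sarcomere (0.02), histone (0.39), PPAR (-0.15), oxidative stress (0.15), glycolysis (0.02) and oxidative phosphorylation (0.00) calls ended, and the fetal gene programme passed with a median of 0.09. Smooth muscle markers had 0.21 there and passed. Without LD replicate 2 the histone median was 0.91 and the oxidative stress (0.03), glycolysis (0.07), oxidative phosphorylation (0.00), smooth muscle (-0.06) and ion channel (-0.28) calls ended. Without LD replicate 1 the ion channel (-0.28), PPAR (-0.32) and smooth muscle (0.08) calls ended, and medians were 0.28 for sarcomere genes, 0.21 for glycolysis, 0.13 for oxidative stress genes and 0.12 for oxidative phosphorylation. Without sham replicate 1 the ion channel (-0.23), oxidative stress (0.02), glycolysis (0.09) and oxidative phosphorylation (0.04) calls ended, and Hist1h1c differed by 0.35. Without sham replicate 2 the PPAR call ended (-0.30), and medians were 0.29 for histones, 0.17 for oxidative stress genes and 0.11 for oxidative phosphorylation. Without sham replicate 3 the fibroblast median was 0.06 and that of oxidative stress genes 0.12, Hist1h1c differed by 1.39, and the PPAR (-0.27), glycolysis (0.09), oxidative phosphorylation (-0.02) and smooth muscle (0.18) calls ended. The glycolysis call also ended without TAC replicate 1 or 2 (0.13). The means of sarcomere genes were 0.06, 0.13 and 0.43 in LD replicates 1, 2 and 3. Those of fibroblast markers were 0.163, 0.227 and 0.234 in LD, beside 0.19, 0.02 and -0.21 in sham, so LD replicate 1 did not exceed sham replicate 1. Core clock genes changed in either direction (fry mixed adjusted p = 3e-04): Dbp at 18.7 ± 7.80 against 3.68 ± 1.53 FPKM (log2 2.05 ± 0.32, adjusted p = 0.0667), Nr1d1 at 1.22 ± 0.30, Arntl at -1.03 ± 0.29 and Nfil3 at -0.69 ± 0.27. The acute phase gene Serpina3n was at 16.2 ± 1.79 against 6.09 ± 1.26 (1.29 ± 0.25). Lower with small p were Klf4, a transcription factor gene of vessels and epithelia (33.5 ± 10.8 against 73.1 ± 6.38), Tnfrsf25 (5.29 ± 1.47 against 18.6 ± 5.27), Misp, Hist1h3d and Cox20. Cox20 stood at 0.58 ± 0.233 against 20.4 ± 4.01, but its exons overlap those of Hnrnpu in the annotation and it was also under 1.1 in TAC replicates 1 and 3, so its value is uncertain. Exons of Dbp, Nr1d1, Dusp1, Myl3, Tnni3, Manf, Ndufs1, Tagln, Esrra, Ube2c and Haghl also overlap another coding gene, and whether reads were assigned by strand is not stated in the labels.

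No gene passed in LD against sham by limma (581 with unadjusted p under 0.05, 173 higher and 408 lower, about 569 by chance; 1506 or 13.2% without overlap, where chance gives 10%), while voom called 3, voom with quality weights 14, the fit of these 2 groups alone 10, limma with library weights 135, and limma without TAC replicate 1, 2 or 3 or sham replicate 3 gave 8, 2, 1 and 1. The library weights were 0.738, 4.743 and 0.397 for LD replicates 1, 2 and 3, so the LD mean behind those 135 calls rested mostly on LD replicate 2. Of 10 groupings of the LD and sham libraries, 1, the real one itself, reached 581 genes at unadjusted p under 0.05, and the others gave 181 to 558. With 10 groupings a share under 0.05 cannot be reached. In LD against sham the median gene differed by -0.11, and by -0.005 after median-of-ratios scaling, so here too the surplus of lower genes cannot be told apart from the shift. Of 47 lists 13 passed, 11 higher and 2 lower, 8 without LD replicate 2 and none with an estimated correlation or by fry's directional test.

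The pathways named in the study's title did not pass as lists in any of the 3 comparisons. In TAC against sham, LD against TAC and LD against sham, the medians were 0.07, -0.15 and -0.08 for the ERK cascade, 0.01, -0.14 and -0.12 for the p38 and JNK cascades, and -0.02, -0.10 and -0.14 for the PI3K-AKT pathway, beside the median gene's 0.00, -0.10 and -0.11. Camera's adjusted p were 0.566 or more. Of the kinases themselves, Mapk3 (ERK1) differed by 0.15 ± 0.22 in TAC against sham and -0.33 ± 0.22 in LD against TAC and Mapk8 (JNK1) by -0.30 ± 0.25 and -0.05 ± 0.25. Akt1 differed by -0.02 ± 0.26 and 0.27 ± 0.26, and Akt2 by -0.34 ± 0.25 and 0.22 ± 0.25. Mapk14 (p38 alpha) was listed at or under 0.57 FPKM in every library and was not tested. In LD against TAC the members of smallest p were Nras (-0.82 ± 0.29) and Rps6ka1 (0.79 ± 0.32) of the ERK list and Pik3ca (-0.82 ± 0.31, and -0.45 without LD replicate 3) of the AKT list. These are transcript levels, and phosphorylation was not analysed here.

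Across the 3 groups the moderated F test by limma called no gene (8 without TAC replicate 1, and 1 without TAC replicate 2 or sham replicate 3), with a smallest adjusted p of 0.0699 and 769 of 11380 genes at unadjusted p under 0.05. Voom called 3 genes and voom with quality weights 5. Whether LD moved expression back towards sham was asked over all 11380 genes. The differences TAC minus sham and LD minus TAC share the TAC libraries, so they correlate with no effect at all: r was -0.56 across genes, against -0.50 in simulated unchanged groups, and the covariance was -0.0853 against -0.0637. In an exact permutation test over the 20 ways to assign the TAC and LD labels, 6 gave a covariance difference as far below 0 (one-sided p = 0.3, where 0.05 is the smallest possible). The return slope of 2.21 rests on a variance between TAC and sham of 0.0098 beyond the error, and has no stable value. The differences of TAC and of LD from sham, which share the sham libraries, correlated at 0.38, against 0.50 in the simulated groups, with a covariance of 0.0518 against 0.0636. The simulation gave each group the same spread. Real replicates correlated at 0.96 to 0.97 in sham, 0.91 to 0.95 in TAC and 0.94 to 0.97 in LD. Unequal spread would move both simulated correlations, so the gaps from -0.50 and 0.50 cannot be read as effects.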

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

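Of the genes named, 42 of 44 kept their direction under every alternative in TAC against sham, 50 of 60 in LD against TAC and 35 of 40 in LD against sham. Of these genes 7, 0 and 18 passed limma's threshold under some alternative. Of the lists called, 9 of 17, 1 of 15 (matrix genes) and 5 of 13 passed under all 23 alternatives other than the estimated correlation and fry's directional test, which called 0 lists in each comparison. With the filter at a mean FPKM of 5, limma called 2 genes in TAC against sham, 0 in LD against TAC, 3 in LD against sham and 2 by the F test. Library weights, of which LD replicate 2 had by far the largest (4.743), gave 9, 0, 135 and 44, voom 4, 0, 3 and 3, and voom with quality weights 6, 0, 14 and 5. An adjusted p under 0.1 gave 2, 0, 3 and 2, unadjusted p under 0.05 with at least a 2-fold change 169, 212 and 142, and a fit of the 2 groups alone 10 in LD against sham. Leaving out 1 library at a time gave 0 to 13, 0 to 0, 0 to 8 and 0 to 8 genes, and 14 to 17, 11 to 17 and 8 to 14 lists. With TAC replicate 3 and LD replicate 3 both left out, 9 lists passed in LD against TAC, and with the length and GC trend removed 8 in LD against sham. The return slope was -2.26 to 19.5 when 1 library was left out, 6.68 with equal sums and 0.477 with both of those libraries left out. It was not run on only the genes called in TAC against sham, since none was called. The replicate number as a block left 0 genes in each comparison, gave 17, 16 and 12 lists, and moved the slope to 0.864. Libraries with the same number correlated between -0.236 and 0.146, and 0 of 9 libraries had its own number as the best match in both other groups. Sham replicate 2 had its highest correlation with TAC replicate 2 (0.146), but in LD it matched replicate 3 best (0.111). The voom fits, the trend removal and the removal of both libraries were chosen after seeing the data. The shallowest library, LD replicate 1, held 7.43 M fragments, which limits low genes most there.

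The values below are log2 differences, or list medians, that turned against the sign of the reported value, and the cause was not tested. With equal sums, in TAC against sham the p38 and JNK cascades -0.01, in LD against TAC Wisp2 -0.08, glucocorticoid-responsive genes -0.12 and in LD against sham Col1a1 -0.04, oxidative phosphorylation -0.06. With the filter at a mean FPKM of 5, in LD against TAC clock genes 0.02, glucocorticoid-responsive genes -0.05 and in LD against sham clock genes 0.23. With TAC replicate 3 and LD replicate 3 both left out, in TAC against sham Col3a1 -0.04, the p38 and JNK cascades -0.07, in LD against TAC Acta1 0.04, Atp2a2 0.01, Mapk8 0.10, Akt2 -0.08, the p38 and JNK cascades 0.02, the PI3K-AKT pathway 0.02, glycolysis -0.05, clock genes 0.05, glucocorticoid-responsive genes -0.07, ribosomal proteins -0.04 and in LD against sham Myh6 -0.14, Col1a1 -0.18. With library weights, in TAC against sham Akt1 0.03, the p38 and JNK cascades -0.03, in LD against TAC Nppa -0.21, Mapk8 0.02, Akt1 -0.01, Wisp2 -0.13, immediate early genes -0.02, clock genes 0.10 and in LD against sham Myh6 -0.16, Col1a1 -0.18, Mapk3 0.05, the ERK cascade 0.02. With median-of-ratios scaling, in TAC against sham the p38 and JNK cascades -0.01, in LD against TAC Acta1 0.13, Atp2a2 0.06, Mapk8 0.07, Comp 0.13, the PI3K-AKT pathway 0.03, clock genes 0.07 and in LD against sham the ERK cascade 0.02. With no filter beyond detection, in TAC against sham the p38 and JNK cascades -0.02, glucocorticoid-responsive genes 0.01. With quantile normalization, in LD against TAC Mapk8 0.10, Comp 0.10, clock genes 0.05 and in LD against sham Myh6 -0.04, oxidative phosphorylation -0.08. With the length and GC trend removed, in TAC against sham Akt1 0.14, the PI3K-AKT pathway 0.02, in LD against TAC Atp2a2 0.01, Mapk8 0.24, Wisp2 -0.01, glucocorticoid-responsive genes -0.06 and in LD against sham oxidative phosphorylation -0.08. With voom, in TAC against sham the p38 and JNK cascades -0.03. With voom and quality weights, in TAC against sham Akt1 0.01, in LD against TAC Nppa -0.04, Mapk8 0.03, Wisp2 -0.03, clock genes 0.08 and in LD against sham Myh6 -0.10, Col1a1 -0.09. Ranges when 1 library was left out were in TAC against sham Col3a1 -0.04 to 0.89, Akt1 -0.11 to 0.15, the p38 and JNK cascades -0.07 to 0.09, the PI3K-AKT pathway -0.11 to 0.05, clock genes -0.19 to 0.08, in LD against TAC Nppa -0.37 to 0.77, Nppb -0.13 to 0.86, Acta1 -0.57 to 0.41, Atp2a2 -0.23 to 0.05, Postn -1.82 to 0.17, Mapk8 -0.15 to 0.06, Akt2 -0.01 to 0.34, Comp -0.34 to 0.32, Wisp2 -0.22 to 0.28, clock genes -0.14 to 0.02, glucocorticoid-responsive genes -0.25 to 0.22, ribosomal proteins -0.03 to 0.35 and in LD against sham Myh6 -0.14 to 0.24, Col1a1 -0.18 to 0.24, Col3a1 -0.49 to 0.02, Fos -0.35 to 0.01, oxidative phosphorylation -0.02 to 0.12, smooth muscle markers -0.06 to 0.21.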

Other observations

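Cytokine and chemokine genes changed in either direction between LD and TAC by fry's mixed test (adjusted p = 0.019), with a median of -0.40 and a camera adjusted p of 0.391. Besides the fibroblast and erythroid markers, which fell, these markers of other cell types did not pass in LD against TAC: macrophages (median -0.27, camera adjusted p = 0.154), endothelium (-0.18, 0.278), smooth muscle (0.02, 0.598) and atrial myocytes (-0.12, 0.921). Calcium handling genes had medians of -0.01, -0.18 and -0.23 in TAC against sham, LD against TAC and LD against sham, and heat shock proteins -0.07, -0.17 and -0.21, none past the threshold.

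The tests of time of day and of exon overlap below were chosen only after seeing the results they measure. Oxidative phosphorylation and ribosomal protein genes are short (median recovered lengths of 764 and 828.5 bases, against 3440.5 for all tested genes), and log2 differences between LD and TAC fell with gene length (rho = -0.209). Differences between LD and TAC rose more strongly with GC content (rho = 0.35), while those between TAC and sham fell with it (rho = -0.236). Median GC contents were 50.2% and 51.3% for these lists, against 50% for all tested genes. After each library's trend on length and GC content was removed, the lists kept at least 0.427 of their excess over all genes: 0.16 from 0.33 for oxidative phosphorylation (adjusted p = 0.0142) and 0.131 from 0.307 for ribosomal proteins (adjusted p = 0.0651). So the trend can be part of the pattern, and the test cannot tell how much. With TAC replicate 3 and LD replicate 3 left out, the lowest share kept was -0.104, with an excess of 0.058 (adjusted p = 0.519) and -0.032 (adjusted p = 0.312). This is what these 2 libraries would give as the cause, and an effect of the decoction on these lists was not separable from them.

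Clock genes differed in LD from both other groups, which could reflect the hour at which tissue was taken, since the labels give no hour. The arm of Dbp and Nr1d1 (9 genes) exceeded the arm of Arntl (5 genes) by 0.953 in LD against TAC, 0.924 in LD against sham and 0.014 in TAC against sham, as a shift in hour would give and as an effect of the decoction on the clock would also give. The data cannot tell these apart. After the length and GC trend was removed the difference was 1.006, so that trend does not account for it.

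Some expressed genes differed widely between replicates: 28 of 6811 genes with a mean FPKM of at least 5 differed at least 8-fold between replicates of a group. Of these, 32.1% overlap exons of another coding gene, against 21.6% of the others (Fisher's exact p = 0.172), and the lowest value lay in the smallest library of its group for 50% (14 of 28, exact binomial p = 0.0714). Neither overlap nor depth could be told from chance, and no biological explanation was tested.

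The 6 libraries of a comparison split into groups of 3 in 10 ways, the real one included. Since the real count of genes is 0, all 10 of 10 reach it by construction, and only the highest other count tells anything: 0 in TAC against sham, 1 in LD against TAC and 1 in LD against sham. As many lists as in the real grouping came in 2 of 10 for TAC against sham (17, highest other 18), and in 1 of 10, the real grouping itself, for LD against TAC (15, highest other 11) and for LD against sham (13, highest other 12). With 10 splits a share under 0.05 cannot be reached. Of 100 splits of all 9 libraries, the real one included, all 100 reach the real 0 genes of the F test by construction, with a highest other count of 3. Genes at unadjusted p under 0.05 by the F test numbered 769, and 30 of the 100 splits, the real one included, gave as many (highest other 1653).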
